A study of Danio rerio with 3 samples.

How the data were processed

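Single-cell RNA sequencing libraries from the telencephalon of adult zebrafish were used, 1 library for each of 3 groups: fish injected with amyloid-beta 42 (AB42), with interleukin-4 (IL4) or with phosphate-buffered saline (PBS), the control. Cells positive and negative for GFP under the her4.1 promoter, a reporter of radial glia, were sorted and mixed in equal number before capture on the 10x platform, per the labels. The sort therefore sets in part how many cells of each type a library holds. The fish were kept at 28 °C with 14 h of light and 10 h of dark, per the labels' protocols.

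The authors deposited a table of counts for each library, with genes in rows and cell barcodes in columns, holding whole-number counts of unique molecular identifiers (UMIs) that were not normalised. The submitters' processing notes name Cell Ranger, STAR and Seurat and the genome build danRer10. Versions and the authors' filters on cells are not given in the sources used here. The 3 tables list the same 28952 gene names, and the names were used as the tables give them. Near-identical gene copies (the her4 genes, her15.1.1, the hsp70 genes and the haemoglobin genes) share reads, so the split of counts among them is uncertain.

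The deposited tables held 910 barcodes for PBS, 1171 for AB42 and 661 for IL4. Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which left 901, 1154 and 661 cells and removed 26, all by their mitochondrial share. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes among genes detected in at least 3 cells were centred, scaled and limited to 10 SD. From these, 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 0.8 were computed on the cells of the 3 libraries together, without batch integration. Scrublet, run per library through scanpy, called 11 of the 2716 cells doublets, or 0.405%; these cells were kept, and their removal was an alternative. The work used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.

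The markers of each cell type were fixed before the data were examined, and the scoring was set afterwards. A cluster took the name of the class with the most markers among its 10 leading genes (those with the largest fold over all other cells and at least 30 UMIs), with ties settled by the number of markers raised at least 2-fold with at least 5 UMIs. At least 5 raised markers were required, or 10 where no marker was among the 10 leading genes, and a haemoglobin share of at least 20% of UMIs for an erythrocyte name. These limits were set after seeing the data. They left 3 of 24 clusters unnamed, with 2.44% of the PBS cells, 7.28% of the AB42 cells and 4.84% of the IL4 cells. No named cluster had more markers of another class than of its own among its 10 leading genes. Names end in "-like" because the labels give no annotation of the cells, and immature and mature neurons were joined in 1 class.

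With 1 library per group there is no replicate, so no test across samples was possible and no p-value was computed. UMIs were summed per library and class and given as CPM, scaled to the total UMIs of that class in the library. Shares of cells carry exact Clopper-Pearson intervals, and ratios of CPM carry exact conditional intervals, all at 95%. Intervals and limits cover counting error only, not the spread between fish or libraries. Those of CPM and of CPM ratios also leave out the spread between cells. They count each UMI as independent, although 1 cell can hold most UMIs of a gene. Where a gene had 0 UMIs in 1 library, its fold is a lower bound against 3 UMIs in that library and class. Classes with at least 30 cells in both libraries were compared: radial glia-like, neuron-like, cycling progenitor-like and oligodendrocyte lineage-like cells for all pairs, and epithelial-like cells for IL4 against PBS only.

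Gene lists were fixed before the data were examined. For each list, the median log2 ratio of CPM with a pseudocount of 10 CPM was taken over the members with a mean of at least 20 CPM in the 2 libraries. It was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5, as a description of these libraries. Members at least 1.5-fold apart were counted as a description of size. Genes named in the text were chosen by a rule fixed beforehand. Genes with at least 30 UMIs and at least 10 cells in the library where they were higher were ranked by the bound of their interval nearest 1. In radial glia-like cells the first 6 in each direction were taken, and in neuron-like cells the first 4; for AB42 against IL4, the first 3 in radial glia-like cells. Mitochondrial, ribosomal and haemoglobin genes and genes with clone-based names were left out of this ranking. Lists that stood apart gave their members with the bounds farthest from 1, and a fixed set of genes was given whatever their values, in full only for radial glia-like cells against PBS. A member that this rule selected in neuron-like cells is not reported here. Other genes named in the text were chosen after their values were seen.

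To compare the share of cells with UMIs of DNA replication and mitosis genes, each cell was thinned to 2489 UMIs, the 20th percentile of radial glia-like cells, and shallower cells were left out. The similarity of the AB42 and IL4 ratios to PBS across genes of at least 50 CPM was set beside 100 simulated draws with no effect and the shared PBS library.

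The ratio, interval, naming and list steps were tested on simulated data drawn from the real levels and library sizes, with 200 genes changed. In radial glia-like cells, a 2-fold change was recovered for 92.6% of changed genes for AB42 against PBS (4300 genes) and for 93.4% for IL4 against PBS (4452 genes), and a 4-fold change for 100% in both. In neuron-like cells the 2-fold and 4-fold figures were 85.1% and 100% for AB42 against PBS (5305 genes) and 74.3% and 93.9% for IL4 against PBS (5384 genes). In cycling progenitor-like cells they were 37.7% and 76.6% for AB42 against PBS (4672 genes) and 48.1% and 90.4% for IL4 against PBS (4783 genes). In oligodendrocyte lineage-like cells they were 21.7% and 57.4% for AB42 against PBS (4739 genes) and 15.2% and 38.6% for IL4 against PBS (5453 genes). In epithelial-like cells they were 18% and 73% for IL4 against PBS (4228 genes). Intervals held the simulated ratio for 95.7% of genes for AB42 against PBS and 96.1% for IL4 against PBS in radial glia-like cells. This was built in, since the draws were Poisson counts of summed UMIs, for which the intervals are exact. The draws had no spread between cells, so the recovery figures may be too high for genes held by few cells. Of 40 unchanged lists of randomly drawn genes per comparison, at most 3 stood apart.

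Alternatives fixed before the data were examined were stricter or no cell filters, resolutions 0.4 and 1.6, removal of doublets, clustering each library alone, a class from each cell's own marker score, other scalings, the mean of each cell's own CPM, thinned cells, pseudocounts of 1 and 50 CPM, other minimum levels and PBS cells split at random. After seeing the data, 3 more were added: leaving out clusters of at least 20 cells with over 70% of them from 1 library, CPM without GFP and the clone-named gene with the most UMIs, and clusters weighted as in the comparison library. Alternatives for lists and genes kept the classes of the main run, so they do not cover which cells belong to a class.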

Results

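Single-cell transcriptomes were collected from the adult zebrafish telencephalon after injection of AB42, the peptide that accumulates in the plaques of Alzheimer disease, of IL4, a cytokine, or of PBS. The series asks how AB42 and IL4 affect the plasticity of neural stem cells, which in this tissue are radial glia. Each group was 1 library, so no difference given here has a replicate check, and every comparison is between libraries. The deposited tables held 3225438 UMIs for PBS, 3670718 for AB42 and 2315335 for IL4. In the 901, 1154 and 661 cells kept, the median depth was 2350, 2432 and 2117 UMIs and the median number of detected genes was 982, 1001.5 and 912. GFP transcripts from the reporter took 3.30%, 2.43% and 4.05% of UMIs in PBS, AB42 and IL4.

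Neuron-like cells were the largest class in each library, followed by radial glia-like cells. The sort mixed GFP-positive and GFP-negative cells in equal number, so these shares are those of the sorted mixture and not of the tissue. Neuron-like cells made up 49.6% of the PBS library (95% interval 46.3 to 52.9%, 447 cells), 52.9% of the AB42 library (49.9 to 55.8%, 610 cells) and 40.4% of the IL4 library (36.6 to 44.2%, 267 cells). Radial glia-like cells made up 28.2% (25.3 to 31.3%, 254 cells), 26.3% (23.8 to 29.0%, 304 cells) and 33.0% (29.4 to 36.7%, 218 cells). Cycling progenitor-like cells, named from genes of DNA replication and mitosis, were less frequent in AB42, with 3.99% (2.93 to 5.28%, 46 cells) against 10.1% in PBS (8.21 to 12.3%, 91 cells) and 8.77% in IL4 (6.73 to 11.2%, 58 cells). Of its 3 clusters, cluster 7, led by ascl1a and dld beside replication genes (mcm2, mcm6), was 8.10% of PBS and 2.95% of AB42. Cluster 17 was 1.55% and 0.607%. Cluster 24, led by mitosis genes (nusap1, cdk1, plk1), was 0.444% (4 cells) and 0.433% (5 cells), so a fall in mitotic cells is not read from the class share. Microglia or macrophage-like cells, the resident immune cells of the brain, were 0.444% of PBS (0.121 to 1.13%, 4 cells), 2.43% of AB42 (1.62 to 3.49%, 28 cells) and 2.57% of IL4 (1.51 to 4.09%, 17 cells). Epithelial-like cells were 4.33%, 1.91% and 4.54% of the PBS, AB42 and IL4 libraries, and oligodendrocyte lineage-like cells 4.11%, 4.77% and 4.69%. Lymphocyte-like cells were 0.777%, 0.433% and 1.21%. Among cycling and radial glia-like cells together, cycling cells were 26.4% in PBS (21.8 to 31.4% of 345 cells), 13.1% in AB42 (9.79 to 17.1% of 350) and 21% in IL4 (16.4 to 26.3% of 276).

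The class sizes moved with the cell filter and the clustering. Over all alternatives, the share of cycling progenitor-like cells ranged from 2.22 to 12.5% in PBS, from 1.35 to 5.20% in AB42 and from 3.34 to 13.5% in IL4. With each library clustered alone the order of PBS and AB42 turned, with 2.22% in PBS against 4.94% in AB42. The lower share of epithelial-like cells in AB42 turned as well, with 6.50% against 0 in PBS and IL4 when each library was clustered alone, and 5.8% against 3.22% and 3.63% when each cell was classed by its own marker score. Over all alternatives it ranged from 1.91 to 6.50% in AB42, from 0 to 5.14% in PBS and from 0 to 6.85% in IL4. That of oligodendrocyte lineage-like cells ranged from 3.94 to 6.93%, from 3.74 to 5.44% and from 0 to 6.05%. That of microglia or macrophage-like cells ranged from 0.117 to 1.89% in PBS, from 1.97 to 3.16% in AB42 and from 1.36 to 3.63% in IL4. Without the clusters of which over 70% came from 1 library, an alternative chosen after seeing the data, neuron-like cells were 45.0% and radial glia-like cells 32.1% of the AB42 library.

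**Figure D1:**
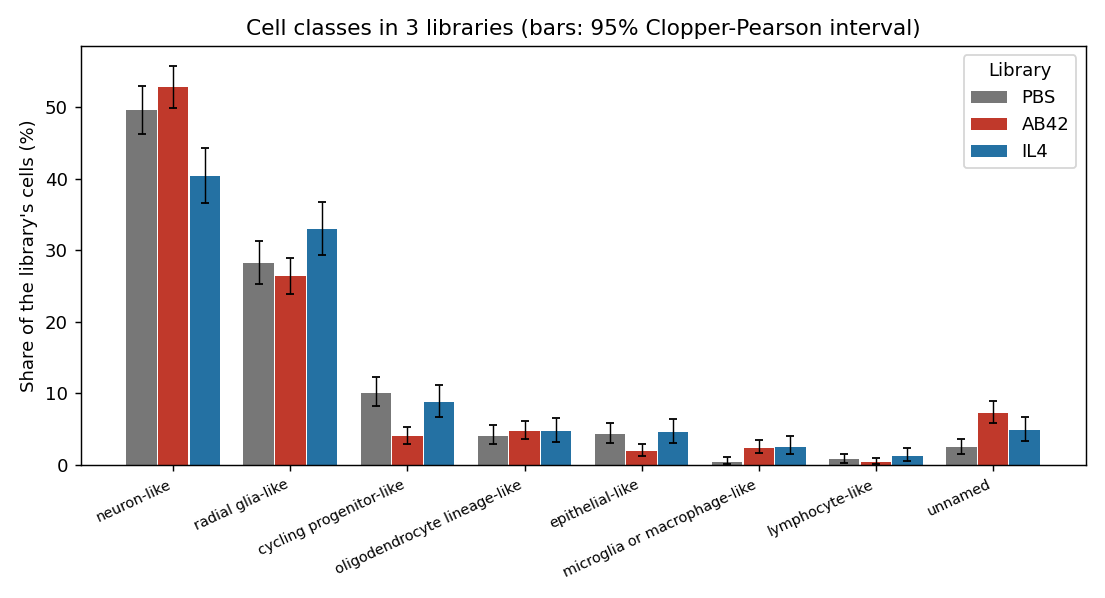
Share of cells (%) in each named class, with 1 bar per library (PBS, AB42, IL4) and 95% Clopper-Pearson intervals, which cover counting error only. The cycling progenitor-like bar stood at 3.99% in AB42 against 10.1% in PBS, and the microglia or macrophage-like bar at 0.444% in PBS against 2.43% in AB42 and 2.57% in IL4.

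Radial glia-like cells fell into 4 clusters, and cluster 1 was the largest in each library, with 58.3% of the class in PBS, 61.8% in AB42 and 41.7% in IL4. Cluster 4 held 35.0% (29.2 to 41.3%) in PBS, 16.8% (12.8 to 21.5%) in AB42 and 40.4% (33.8 to 47.2%) in IL4. Interferon-induced genes (rsad2, isg15) and lgals1l1 led cluster 4, and these genes also differed between libraries, so its size and their levels are not separate results. Cluster 11, led by ntn1b and sulf1, held 6.69% (3.95 to 10.5%) in PBS, 14.8% (11 to 19.3%) in AB42 and 17.4% (12.6 to 23.1%) in IL4. At resolution 0.4, clusters 1, 4 and 11 all matched 1 joint cluster of 254 PBS, 280 AB42 and 222 IL4 cells. At resolution 1.6 they had separate matches, so the differences between them depend on the resolution. Cluster 21, led by cd81b, ndnf and nog3, held 6.58% in AB42 (4.06 to 9.98%), 0.459% in IL4 and 0 of 254 cells in PBS. Neuron-like cells fell into 9 clusters. Cluster 2, led by neuropeptide genes, was the largest in PBS (30.6%) and IL4 (40.4%), against 14.4% in AB42. In AB42 the largest was cluster 6, led by synpr, sst3, cart2 and tac1, with 27.7% of the class (24.2 to 31.4%, 169 cells) and 0 cells in the other libraries. A cluster from 1 library may be a trait of that library and not a cell type.

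**Figure D2:**
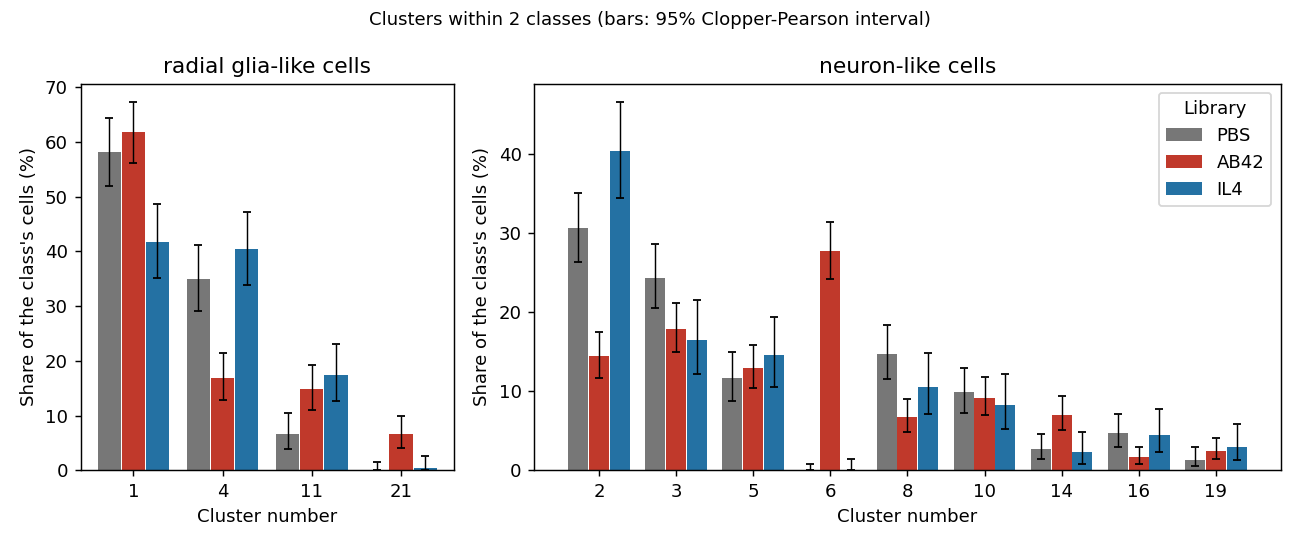
Share (%) of each cluster among the radial glia-like cells (left) and the neuron-like cells (right) of the PBS, AB42 and IL4 libraries, with 95% Clopper-Pearson intervals. Cluster 6 held 27.7% of the neuron-like cells in AB42 and none in the other libraries, and cluster 4 held 16.8% of the radial glia-like cells in AB42 against 35.0% in PBS and 40.4% in IL4.

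The comparison of AB42 with PBS in radial glia-like cells addresses the effect of the peptide on neural stem cells. Heat shock genes were higher and interferon response genes lower in the AB42 library. The inducible chaperone genes hsp70.1 and hsp70l stood at 833 against 119 CPM (7.03-fold, 5.97 to 8.32) and at 2081 against 414 CPM (5.02-fold, 4.59 to 5.50). The transcription factor gene sox2, which maintains neural stem cells, was 4.33-fold lower, with a ratio of 0.231 (0.199 to 0.268). Its ratio to IL4, given below, was nearer 1, so sox2 was lower in IL4 than in PBS too. The radial glia identity list, which holds sox2, did not stand apart in this comparison. The cysteine protease inhibitor gene cst3 was at 61.0 CPM in AB42 and 595 CPM in PBS, 9.75-fold lower (7.75 to 12.4). Of the 25 fixed lists, 7 stood apart from random lists, 4 higher and 3 lower, where 1.25 would for lists of unrelated genes. Genes of 1 list can move together and near-identical copies share reads, so a number above 1.25 is not an excess over chance. With CPM scaled without mitochondrial and ribosomal protein genes, 4 lists were higher and 5 lower.

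Of 18 measured heat shock and chaperone genes, 8 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.41. These included hsp90aa1.2 (3.60-fold, 3.31 to 3.92) and hspb1 (3.72-fold, 2.96 to 4.70). Of 10 mitochondrially encoded genes, 4 were at least 1.5-fold higher (median 0.51), among them mt-co1 (1.62-fold, 1.54 to 1.71) and mt-co2 (1.6-fold, 1.55 to 1.66). Of 10 interferon response genes, 5 were at least 1.5-fold lower (median -0.45). They included irf8, a myeloid transcription factor gene (ratio 0.140, 0.0614 to 0.281), rsad2 (0.364, 0.294 to 0.447) and isg15 (0.444, 0.391 to 0.504). The median was -0.44 with clusters weighted as in PBS. The marker list of radial glia was lower too (median -0.25, 4 of 20 at least 1.5-fold lower), with her4.3 at a ratio of 0.530 and slc1a3b, a glutamate transporter gene, at 0.582. These lists stayed apart in all 13 alternatives.

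The other lists that stood apart did not do so in each alternative. Lysosomal genes were higher (median 0.22, 2 of 16 at least 1.5-fold higher: ctsla 1.56-fold and lamp2 1.62-fold), but at 0.05 without the clusters mostly of 1 library. Immediate early genes, which are induced by activity and stress, were higher (median 0.18, 7 of 35 higher and 1 lower: mcl1b 1.95-fold, egr4 1.82-fold), but the sign turned to -0.023 for the mean of each cell's own CPM. Antigen presentation genes were lower (median -0.40, 2 of 6 lower: cd74b at 0.420 and b2m at 0.632), which was lost among members of at least 100 CPM (-0.27). Neurotransmitter identity genes were lower (median -0.47, 3 of 6 lower and 1 higher), with the somatostatin gene sst1.1 at 273 against 1116 CPM, but their median was -0.07 without a minimum level. Of the sst1.1 UMIs, 5 cells held 60.6% in AB42 and 27.5% in PBS, and whether they belong to radial glia or to neurons captured with them was not tested. Markers of ciliated cells, with foxj1a at 1.76-fold, were higher (median 0.61 over 3 genes), and their median was 0.19 in thinned cells. Notch pathway genes had a median of -0.08 and Alzheimer disease genes one of 0.10, both inside the range of random lists.

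Among genes named by size, the highest in AB42 was the tetraspanin gene cd81b, with 203 UMIs against 0 (at least 73.6-fold). Its UMIs lay in 20 cells, and it led cluster 21; without clusters mostly of 1 library its log2 ratio was 0.50. The mitochondrial thiolase gene acaa2 was at 156 against 5.61 CPM (27.8-fold, 13.8 to 65.1). TYMP, a thymidine phosphorylase gene, was 8.84-fold higher (4.23 to 21.3) and syt9b, a synaptotagmin gene, 16.3-fold higher from 30 against 2 UMIs (4.14 to 141); without clusters mostly of 1 library the log2 ratio of syt9b was 0.54, against 1.53. Lower in AB42 were clec19a, with 0 against 36 UMIs (at least 11-fold), and anxa11a, an annexin gene (20.4-fold, 7.71 to 76.7). So were lix1 (8.39 against 114 CPM, 13.5-fold, 7.37 to 27.6), adh8b (1 against 47 UMIs, ratio 0.0232, 0.000574 to 0.135) and cox7a1 (1 against 43 UMIs, ratio 0.0253, 0.000626 to 0.149). Of the fixed genes, her4.1 had a ratio of 1.07 (1.03 to 1.11), her4.2 0.807 (0.775 to 0.840), gfap 0.871 (0.784 to 0.968), fabp7a 0.778 (0.765 to 0.790) and s100b 0.983 (0.918 to 1.05). The interleukin-4 receptor gene il4r.1 was at 0.97 (0.631 to 1.5), appa at 1.05, appb at 1.11 and pcna at 0.793 (0.557 to 1.12). The apolipoprotein gene apoeb was 4.93-fold higher (2.79 to 9.29) from 68 against 15 UMIs, of which 33.8% lay in 1 AB42 cell. UMIs of stat6 and mki67 numbered 5 and 0 in AB42 and 3 and 3 in PBS, and il1b had 0 in both.

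In neuron-like cells, AB42 against PBS, heat shock genes were again higher, and lysosomal genes were lower. Different clusters hold the largest part of this class in the pair of libraries, cluster 6 in AB42 and cluster 2 in PBS. Of 21 heat shock genes, 14 were at least 1.5-fold higher and 0 lower (median 0.87), with hsp70l at 7312 against 1559 CPM (4.69-fold, 4.44 to 4.96), dnajb1b at 3.28-fold (2.77 to 3.90) and the small heat shock gene hspb1 at 371 against 3 UMIs (81.4-fold, 27.6 to 396); without clusters mostly of 1 library the log2 ratio of hspb1 was 3.18, against 4.36. Of 15 lysosomal genes, 4 were at least 1.5-fold lower (median -0.32), among them the cathepsin genes ctsba (ratio 0.524, 0.390 to 0.702) and ctsd (0.605, 0.491 to 0.744). Both lists stayed apart in all 13 alternatives. In all, 11 of 25 lists stood apart, 6 higher and 5 lower, where 1.25 would for lists of unrelated genes.

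The remaining lists in neuron-like cells were lost in at least 1 alternative. Higher in AB42 were oxidative stress genes (median 0.28, 4 of 18 higher and 1 lower, 0.22 at 100 CPM or more), with nfe2l2a at 9.87-fold (4.05 to 31.3), and apoptosis and p53 genes (median 0.38, 3 of 8), with mdm2 at 6.07-fold. Glycolysis genes (median 0.37, 2 of 17) included eno2 at 2.12-fold, and nuclear genes of oxidative phosphorylation (median 0.20, 2 of 57) included atp5o at 1.54-fold. Genes of the interleukin-4 receptor and STAT6 pathway had a median of 0.42 (2 of 6), with jak2a at 3.66-fold and jak1 at 2.74-fold. Without clusters mostly of 1 library these medians were 0.09 for apoptosis and p53, 0.22 for glycolysis, 0.12 for oxidative phosphorylation and 0.20 for the interleukin-4 receptor list. Lower in AB42 were endoplasmic reticulum stress genes (median -0.26, 5 of 23 lower and 1 higher, -0.11 at 100 CPM or more), with pdia3 at 0.570, and mitochondrially encoded genes (median -0.36, 2 of 10, -0.17 for the mean of each cell's own CPM), with mt-nd3 at 0.652. Serotonin and neurotrophin receptor genes were lower (median -0.52, 4 of 7), with htr1ab at 0.219 and htr1aa at 0.286, and turned to 0.012 without a minimum level. Radial glia identity genes were lower (median -0.41, 4 of 11 lower and 2 higher) and turned to 0.10 without it. Immature neuron markers were higher (median 0.46, 5 of 11 higher and 2 lower), with ebf3a at 4.44-fold and dlx5a at 3.18-fold, and 0.28 with clusters weighted as in PBS.

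The vesicle gene synpr was at 1260 against 20.2 CPM in neuron-like cells (62.2-fold, 39.7 to 104), and it leads cluster 6; without clusters mostly of 1 library its log2 ratio was 1.2. The glutamate receptor gene grm6b had 173 against 0 UMIs (at least 38.0-fold) and FAM163A 151 against 1 UMIs (99.4-fold, 17.6 to 3951). Both are leading genes of cluster 14, 1 of the clusters mostly of 1 library. Without those clusters their log2 ratios were 0.30 and -0.15, but with clusters weighted as in PBS they were 1.89 and 1.49. Lower in AB42 were cst3 (30.9 against 690 CPM, 22.3-fold, 16.5 to 31.1) and the sodium channel subunit gene scn2b (7.72 against 164 CPM, 21.3-fold, 11.6 to 43.5). The somatostatin gene sst1.2 was 25.3-fold lower (13.8 to 51.5) and the prodynorphin gene pdyn 15.9-fold lower (10.5 to 25), with 42.6% and 67.8% of the PBS UMIs in 1 cell. The amyloid precursor protein genes were lower, with a ratio of 0.534 (0.489 to 0.583) for appa and 0.586 (0.503 to 0.682) for appb.

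**Figure D3:**
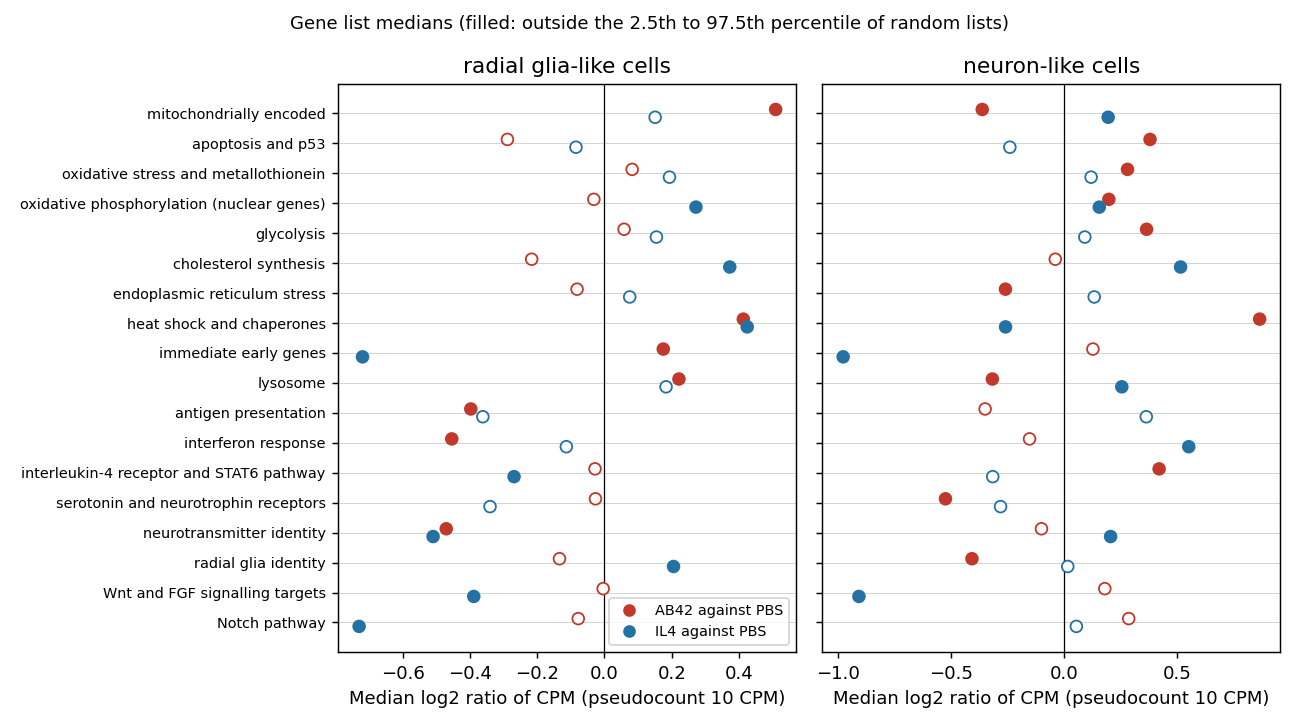
Median log2 ratio of CPM for gene lists in radial glia-like cells (left) and neuron-like cells (right), AB42 against PBS in red and IL4 against PBS in blue, filled where the median lay outside the range of random lists. Heat shock genes were at 0.41 and 0.87 for AB42, and immediate early genes at -0.72 and -0.98 for IL4.

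The comparison of IL4 with PBS in radial glia-like cells addresses the effect of the cytokine on neural stem cells. Notch pathway and immediate early genes were lower in the IL4 library, and genes of cholesterol synthesis, oxidative phosphorylation and heat shock were higher. Notch signalling keeps neural stem cells undifferentiated. Its target genes her2 and her4.3 were at ratios of 0.282 (0.234 to 0.337) and 0.350 (0.312 to 0.392), and the ligand gene dla at 0.307 (0.266 to 0.355). The metallothionein gene mt2 was at 3906 against 705 CPM (5.54-fold, 5.17 to 5.94). Of the 25 lists, 9 stood apart, 4 higher and 5 lower, where 1.25 would for lists of unrelated genes.

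Of 14 Notch pathway genes, 9 were at least 1.5-fold lower and 0 higher (median -0.73). Of 32 immediate early genes, 21 were lower and 1 higher (median -0.72), among them nr4a3 (34 against 181 CPM, 5.32-fold lower, 3.76 to 7.73), egr4 (ratio 0.296, 0.259 to 0.337), junbb (0.399, 0.380 to 0.418) and fosab (0.440, 0.428 to 0.452). Of 20 cholesterol synthesis genes, 6 were higher and 1 lower (median 0.37), with fdps, the farnesyl diphosphate synthase gene, at 1.80-fold (1.59 to 2.05) and hsd17b7 at 1.70-fold (1.37 to 2.11). Of 55 nuclear genes of oxidative phosphorylation, 4 were higher and 2 lower (median 0.27), among them atp5g1 at 1.67-fold (1.44 to 1.93). Of 18 heat shock genes, 6 were higher and 1 lower (median 0.43), with hsp70.1 at 3.84-fold (3.22 to 4.6), hsp70l at 3.29-fold and dnajb1b at 2.37-fold. These 5 lists stayed apart in all 13 alternatives. Radial glia identity genes were higher (median 0.21, 3 of 17 higher and 2 lower), with the glutamine synthetase gene glulb at 2.21-fold (1.97 to 2.49), and 0.11 with clusters weighted as in PBS. The list member sox2 went the other way, as its ratios of AB42 to PBS and to IL4 show. Wnt and FGF target genes were lower (median -0.39, 3 of 6), with spry4 at 0.434, and -0.03 without a minimum level. Genes of the interleukin-4 receptor and STAT6 pathway were lower (median -0.27, 3 of 11), with the feedback inhibitor genes socs3b at 0.565 and socs3a at 0.510, and -0.22 in thinned cells, where the list no longer stood apart. Neurotransmitter identity genes were lower (median -0.51, 3 of 6 lower and 1 higher), with sst1.1 at 0.319, and -0.09 without a minimum level.

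By size, the genes highest in IL4 beside mt2 were acaa2 (109 against 5.61 CPM, 19.5-fold, 9.58 to 46.2) and ube2ia, a SUMO-conjugating enzyme gene (68.0 against 7.01 CPM, 9.70-fold, 4.99 to 21.1). In AB42, ube2ia was also at least 4-fold higher than in PBS, in both radial glia-like and neuron-like cells. The Hes-family gene her8.2 was at 213 against 39.3 CPM (5.43-fold, 4.04 to 7.41), lgals1l1 at 4.78-fold (3.85 to 5.97) and crtac1a at 659 against 161 CPM (4.1-fold, 3.53 to 4.78). Lowest were rom1a, with 0 against 188 UMIs (at least 47.8-fold), and esm1 (14.5-fold, 5.44 to 54.6). They were followed by rab9a (11.9-fold, 4.89 to 37.7), clec19a (1 against 36 UMIs, ratio 0.0364, 0.000897 to 0.216), nr4a3 and her15.1.1 (694 against 2773 CPM, 4.0-fold, 3.70 to 4.33). Of the fixed genes, her4.1 had a ratio of 0.854 (0.817 to 0.893), her4.2 0.615 (0.587 to 0.645), gfap 1.19 (1.07 to 1.32), fabp7a 1.16 (1.14 to 1.18) and s100b 1.15 (1.08 to 1.24). A difference in il4r.1 was not detectable at this depth (ratio 0.983, 0.620 to 1.55), nor were differences in appa (1.07, 0.864 to 1.32), appb (1.1, 0.803 to 1.5), pcna (1.05, 0.747 to 1.48) or apoeb (0.524, 0.167 to 1.43). IL4 had 1 UMI of stat6, 2 of mki67 and 0 of il1b.

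**Figure D4:**
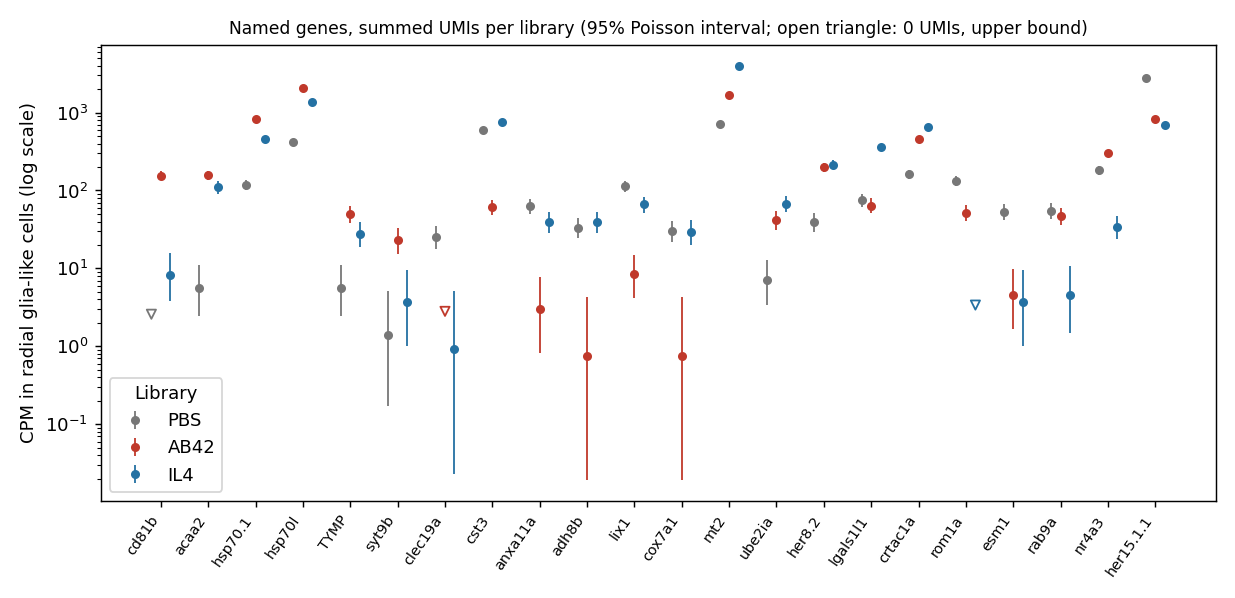
CPM (log axis) of the genes named by size in radial glia-like cells of the PBS, AB42 and IL4 libraries, with 95% Poisson intervals of counting error and an open triangle at the upper bound where a library had 0 UMIs. The gene cst3 stood at 61.0 CPM in AB42 against 595 CPM in PBS, and mt2 at 3906 CPM in IL4 against 705 CPM in PBS.

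In neuron-like cells, IL4 against PBS, immediate early genes were lower and the medians of the other lists were nearer 0 or rested on few genes. Cluster 2 held the largest part of the class in both libraries. Of 31 immediate early genes, 25 were at least 1.5-fold lower and 0 higher (median -0.98), among them npas4b, an activity-induced transcription factor gene (ratio 0.243, 0.178 to 0.325), nr4a3 (0.241, 0.139 to 0.393), nr4a1 (0.341, 0.288 to 0.402) and fosb (0.352, 0.283 to 0.434). This list stayed apart in all 13 alternatives. In all 9 of 25 lists stood apart, 6 higher and 3 lower, and the other 8 were each lost in at least 1 alternative. Wnt and FGF target genes were lower (median -0.91, 3 of 4, -0.15 without a minimum level), with etv5a at 0.302. Heat shock genes were lower (median -0.26, 5 of 20 lower and 1 higher), with hsp90aa1.2 at 0.449 (0.418 to 0.480), and -0.13 with clusters weighted as in PBS. Cholesterol synthesis genes were higher (median 0.52, 5 of 11, 0.23 without a minimum level), with msmo1 at 1.97-fold (1.35 to 2.87). Interferon response genes were higher (median 0.55, 3 of 5, 0.36 with clusters weighted as in PBS), with b2m at 1.53-fold. Lysosomal genes (median 0.26, 5 of 18, cd63 2.42-fold), neurotransmitter identity genes (median 0.21, 4 of 18 higher and 3 lower), nuclear genes of oxidative phosphorylation (median 0.16, 2 of 57 higher and 1 lower) and mitochondrially encoded genes (median 0.20, 2 of 11, mt-nd5 1.55-fold) were also higher. With clusters weighted as in PBS none of these 4 stood apart, at 0.20, 0.015, 0.077 and 0.15.

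Several of the genes named by size in these neuron-like cells rested on few cells. The oxytocin gene oxt had 1841 UMIs in IL4 against 1 in PBS, with 61.9% of them in 1 cell. The proenkephalin gene penka was at 1472 against 110 CPM (13.4-fold, 10.9 to 16.7), with 50.9% of its IL4 UMIs in 1 cell, and otpa at 237 against 11.7 CPM (20.2-fold, 10.9 to 41.7), with 71.2% in 1 cell. More evenly spread was spega, at 137 against 13.9 CPM (9.87-fold, 5.38 to 19.5) in 50 IL4 cells. Lower in IL4 were rom1a (1 against 142 UMIs, ratio 0.0141, 0.000355 to 0.0799), the somatostatin gene sst3 (15.9-fold, 9.68 to 28.0, with 80.4% of its 509 PBS UMIs in 5 cells) and the glutamate transporter gene slc1a7a (9.58-fold, 3.97 to 30.2). The gene pyyb was 5.68-fold lower (3.80 to 8.84), with 78.0% of its PBS UMIs in 1 cell. The ratios of appa and appb were 1.02 (0.920 to 1.13) and 0.980 (0.815 to 1.18).

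Set directly against IL4, the AB42 library had higher immediate early and heat shock genes in both classes and lower cholesterol synthesis genes in radial glia-like cells. In radial glia-like cells the median log2 ratio of all genes was -0.14, so list medians are to be read relative to that value; it was 0.01 with median-of-ratios scaling. Of 31 immediate early genes, 23 were at least 1.5-fold higher in AB42 and 0 lower (median 0.71), with nr4a3 at 8.80-fold (6.27 to 12.7) and egr4 at 6.15-fold (5.43 to 6.99). Of 20 cholesterol synthesis genes, 12 were lower and 1 higher (median -0.73), with dhcr7 at a ratio of 0.144 (0.0589 to 0.309), mvda at 0.258 and fdps at 0.428. Heat shock genes (median 0.31, 8 of 18 higher) and nuclear genes of oxidative phosphorylation (median -0.31, 11 of 54 lower) also stood apart, and these 4 lists did so in all 13 alternatives. Notch pathway genes were higher (median 0.35, 6 of 16 higher), with her6 at 2.2-fold (2.1 to 2.31) and hey2 at 3.11-fold, but 0.13 with clusters weighted as in IL4. Id and BMP genes were higher (median 0.43, 3 of 8), with smad7 at 5.22-fold, and radial glia identity genes lower (median -0.23, 2 of 17), with sox2 at 0.496; both were lost in some alternatives. Synapse genes were higher (median 0.17, 2 of 8), with nrxn1a at 2.61-fold, and turned to -0.10 in thinned cells. Markers of ciliated cells were higher (median 0.94 over 3 genes) and those of erythrocytes lower (median -0.70 over 3 genes); they stood apart in 9 and 8 of 12 alternatives and were at 0.12 and -0.016 without a minimum level. By size, rom1a had 68 against 0 UMIs (at least 18.8-fold), fkbp5, a glucocorticoid-induced gene, 65 against 1 UMIs (54.0-fold, 9.35 to 2164) and cd81b 203 against 9 UMIs (18.7-fold, 9.67 to 41.5), which turned to a log2 ratio of -0.14 without clusters mostly of 1 library. Lower in AB42 were cst3 (12.2-fold, 9.72 to 15.6), adh8b (1 against 43 UMIs, ratio 0.0193, 0.000478 to 0.113) and cox7a1 (1 against 32 UMIs, ratio 0.0259, 0.000637 to 0.155).

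In neuron-like cells, 11 of 24 lists stood apart between AB42 and IL4, with cluster 6 the largest in AB42 and cluster 2 in IL4. Heat shock genes had a median of 1.06 (15 of 21 higher, 0 lower), with hspb1 at 17.4-fold (8.36 to 43.6; log2 ratio 2.26 without clusters mostly of 1 library, against 3.44), and immediate early genes one of 0.91 (23 of 31 higher, 0 lower), with atf3 at 4.55-fold (3.60 to 5.83). Neurotransmitter identity genes had a median of -0.75 (11 of 18 lower, 2 higher), with calb2a at a ratio of 0.0682, and lysosomal genes one of -0.65 (9 of 15 lower), with ctsba at 0.428. These 4 lists stayed apart in all 13 alternatives. Wnt and FGF target genes (median 1.22 over 4 genes, etv5a 3.78-fold) and genes of the interleukin-4 receptor and STAT6 pathway (median 0.89, 4 of 6 higher, arg2 3.06-fold) stayed apart in the 12 alternatives that measured them. Alzheimer disease genes were lower (median -0.39, 7 of 16 lower and 2 higher), with appa at 0.524, in 10 of 13 alternatives. Antigen presentation genes (median -0.60) and mitochondrially encoded genes (median -0.57) were lower and apoptosis and p53 genes (median 0.59) higher, each lost in at least 1 alternative. Endoplasmic reticulum stress genes were lower (median -0.48) and turned to 0.33 among members of at least 100 CPM.

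Epithelial-like cells had enough cells for IL4 against PBS only (30 and 39 cells). Notch pathway genes were higher in IL4 (median 1.11, 11 of 14 at least 1.5-fold higher and 1 lower), with her15.1 at 6.05-fold (4.34 to 8.59), as were the markers of radial glia (median 0.96, 13 of 20 higher and 1 lower), with her4.1 at 3.67-fold (2.95 to 4.59), and of cycling progenitors (median 0.79, 6 of 8). These 3 lists stayed apart in all 13 alternatives, which kept the classes of the main run. With each library clustered alone, no cell of PBS or IL4 took the epithelial-like name, so these results depend on the joint clustering. In all 10 of 24 lists stood apart, 6 higher and 4 lower, and 4 in thinned cells. Immediate early genes were higher here (median 0.30, 12 of 32 higher and 3 lower), against lower values in the other 4 classes, and 0.23 in thinned cells, where they no longer stood apart and the median over all genes was 0.29. Mitochondrially encoded genes were lower (median -0.79, 7 of 10), but -0.40 in thinned cells. The median depth of these cells was 3454.5 UMIs in IL4 and 5380 in PBS, and RNA from radial glia-like cells was not tested as a source of these markers.

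UMIs of DNA replication and mitosis genes were counted in radial glia-like cells. After thinning to 2489 UMIs, the share of these cells with at least 2 UMIs of the list was 86.8% in PBS (81.5 to 90.9%, 35 cells left out), 81.6% in AB42 (76.1 to 86.4%, 70 left out) and 75.6% in IL4 (68.4 to 81.9%, 50 left out). In neuron-like cells, a class that should lack dividing cells, the same share was 86.1%, 78.4% and 87.1%, from the 101, 204 and 31 deepest cells, with 346, 406 and 236 left out. The values in radial glia-like cells lay inside the 95% intervals of this background, and no cycling is read from them. Unthinned, the shares were 95.3%, 84.5% and 86.2% in radial glia-like cells at median depths of 5184.5, 4436.5 and 4345.5 UMIs, and 53.2%, 55.4% and 45.7% in neuron-like cells at 1591, 1586.5 and 1419 UMIs. The list took 1500 CPM in PBS, 1342 CPM in AB42 and 1443 CPM in IL4 in radial glia-like cells, against 12033, 15146 and 16417 CPM in cycling progenitor-like cells.

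The ratios AB42/PBS and IL4/PBS were compared across genes, which are not independent replicates. In radial glia-like cells Pearson's r was 0.397 and Spearman's rho 0.335 over 2129 genes. Simulated libraries with no effect and the shared PBS library gave a mean r of 0.502 (SD 0.0730). In the simulation the genes vary by counting noise alone, so the size of r does not separate a shared effect from the shared control. The covariance was 0.0860 against 0.0155 in the simulation, so the counting noise of the shared control gives a small part of it. With the PBS cells split into random parts, r was 0.306 (0.249 to 0.356 over 100 splits) and the covariance 0.0711. Both parts came from 1 library, so traits of the PBS library that AB42 and IL4 lack are not separated from a shared effect. In neuron-like cells r was 0.136 and rho 0.0552 over 2711 genes, against a simulated r of 0.449, and the covariance was 0.0402 against 0.0267; with split PBS cells r was 0.0329.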

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

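The tests of the olfactory bulb list, of handling, of the treatments and of RNA from other cells were chosen after the results were seen, and those of doublets, depth and chromosomal neighbours before. The 3 clusters that took no name lie outside the comparisons, and each held a larger share of a treated library than of PBS. Cluster 13 was led by epd and haemoglobin genes, but from few of its 67 cells (epd in 2, hbba1.1 in 4, hbaa1 in 3), and as a whole it held 21297 CPM of fabp7a and 73764 CPM of GFP. Its cells had a median of 1210 UMIs and 1163 CPM of gfap, but only 2 radial glia markers were raised. The radial glia-like shares and levels leave this cluster out. It was 3.64% of the AB42 library (2.64 to 4.89%) against 1.11% of PBS and 2.27% of IL4. Cluster 15, led by retinoid and pigment epithelium genes such as rpe65a, rlbp1b and rdh5, was 3.21% of AB42 (2.27 to 4.39%) against 0.999% of PBS and 0 of 661 cells of IL4, which allows a share of up to 0.557%. Cluster 20, led by adma, crabp1a, ptgs2a and krt18, was 2.57% of IL4 (1.51 to 4.09%) against 0.333% of PBS and 0.433% of AB42.

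All 169 cells of neuron cluster 6 came from the AB42 library. Scrublet called 0.592% of them doublets (upper bound 3.25%). It called only 3 of the 1154 AB42 cells and at most 2.94% of any cluster. A low share was thus nearly certain, and it does not argue against doublets as the source of cluster 6. A candidate explanation is that cells of the olfactory bulb, which lies in front of the telencephalon, were taken with the AB42 tissue: the 9 measured genes of a bulb interneuron list without its dlx genes had a median log2 ratio of 2.03 against the other AB42 neuron-like cells, above 100% of random lists. Not all members went this way: among those under the level filter, scgn was at 0 against 14.4 CPM and calb2a at 7.82 against 7.68 CPM. The most abundant were slc32a1 (1095 against 271 CPM) and gad2 (1012 against 275 CPM), but GABAergic neurons of the subpallium use such genes too, 14 of the 21 list genes reached 20 CPM in PBS neurons, 6 are also class markers, and the sort, which kept GFP-negative cells, would not remove these cells. An effect of AB42 cannot be told apart from this, since 100% of the cluster came from 1 library.

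Heat shock genes were higher in AB42 than in PBS in all 4 classes compared (lowest median log2 ratio 0.36), and immediate early genes were lower in IL4 than in PBS in these 4 (highest median -0.49), in oligodendrocyte lineage-like cells in 11 of 13 alternatives. Both sets respond to dissociation and handling, and with 1 library per treatment an effect of handling the AB42 library cannot be told apart from one of the injection for the heat shock genes. Handling that moves all classes alike was examined for the immediate early genes in IL4. Set against the median gene of each class, their members lay higher in epithelial-like than in neuron-like cells in the main run and all 13 alternatives. The difference with the lowest bound was a median of 1.13 (0.52 to 1.33 by resampling the members), in thinned cells. It does not show that these genes rose in epithelial-like cells, where the list was at 0.23 after thinning and the median over all genes at 0.29. Nor does it argue against handling that moves all classes alike. Epithelial-like cells of IL4 had higher radial glia markers, and RNA from radial glia-like cells was not tested as a source. The immediate early gene fosab was at 9853 to 18452 CPM in the 4 radial glia-like clusters and at 6355 CPM in the epithelial-like cluster. A difference in depth is argued against as the whole cause of the immediate early difference in neuron-like cells, which was -1.02 after each cell was thinned to 1 depth. In oligodendrocyte lineage-like cells it was then -0.36, inside the random range, so depth stays open there. Handling that moves all classes alike was also examined for the heat shock genes in IL4. Their members lay higher in radial glia-like than in neuron-like cells in the main run and all 13 alternatives. The median difference was 0.62 (0.12 to 0.97) where the bound was lowest. This pair of classes was compared after their medians had been seen with opposite signs, so a difference was to be found. It therefore does not argue against such handling. The fall in neuron-like cells itself was less firm, at -0.13 and inside the random range with clusters weighted as in PBS. Handling that moves all classes alike stays open for the immediate early genes and for the heat shock genes in IL4. Handling that moves classes differently and an effect of the injections stay open and untested.

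A few genes were at least 3-fold apart in each of the 4 classes: 1 higher (acaa2) and 2 lower (cst3 and 1 clone-named gene) in AB42 against PBS, and 1 higher (ube2ia) and 1 lower (rom1a) in IL4 against PBS. RNA from other cells, which adds a like number of UMIs to each droplet, is argued against for cst3 and rom1a in radial glia-like cells only: in PBS, these cells held 3.04 and 3.96 times as many UMIs of the pair as cycling progenitor-like cells (lowest bound 2.41), where all UMIs differed 1.29-fold. In the other 3 classes it cannot be told apart from RNA of the cells themselves: cst3 was at 1.45 UMIs per neuron-like, 1.1 per cycling progenitor-like and 1.92 per oligodendrocyte lineage-like cell, and the lower of the 2 genes' ratios to cycling cells was 1.32 (1.07 to 1.64) in neuron-like and 1.75 (1.27 to 2.39) in oligodendrocyte lineage-like cells. The higher ones, of rom1a, were 1.7 (lower bound 1.03) and 3.62 (1.88 to 7.14), so only rom1a in oligodendrocyte lineage-like cells lay above the limit of 1.5. For acaa2 free RNA is argued against in radial glia-like cells, which held 16.4 times as many of its UMIs per cell as neuron-like cells in AB42 (10.8 to 25.9), where all UMIs differed 1.84-fold. For the clone-named gene it cannot be told apart, since its ratio in PBS was 2.65 (2.11 to 3.35) and that of all UMIs 2.67. Nor can it for ube2ia in IL4 (1.21, 0.865 to 1.69, against 2.85 for all UMIs). In radial glia-like and neuron-like cells ube2ia was at least 4-fold higher in AB42 than in PBS too, so its difference is not particular to IL4. A variant carried by the fish of 1 library cannot be told apart from other causes: the number of neighbouring genes among the genes at least 4-fold apart lay at percentile 48.4 of random sets, but with 11 (AB42) and 6 (IL4) such genes, random sets held a mean of 0.0277 and 0.005 neighbours, so 0 was nearly certain by chance and could not argue against a variant, which makes the test void. An effect of the injections also stays open, with 1 library each.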

How the results depend on the processing

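The alternatives without clusters mostly of 1 library, with clusters weighted as in the comparison library and without GFP and the most abundant clone-named gene were chosen after seeing the data, and all others before. No paired analysis was possible because each group was 1 library and no test was made. Of 133 list calls, 48 stayed apart in every alternative that measured them: 13 of 28 in radial glia-like, 9 of 32 in neuron-like, 14 of 32 in cycling progenitor-like, 9 of 29 in oligodendrocyte lineage-like and 3 of 12 in epithelial-like cells. Of 1700 list values under alternatives, 1486 kept their call, 199 lost it and 15 changed sign. An alternative that left too few members of a list gave no value. All list and gene alternatives kept the classes of the main run. Of 4833 gene values, 4541 kept their side, 195 lost it, 86 gained it and 11 changed sign. Of 162 class shares 34 and of 99 cluster shares 26 left the interval of the reported value. Depth limits the cycling progenitor-like, oligodendrocyte lineage-like and epithelial-like cells most, where simulated 2-fold changes were found for 48.1% of genes at most. Below, list and gene values are log2 ratios, and where no reason is given the cause was not tested.

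With at least 500 detected genes, radial glia-like cells were 37.1% of PBS, 31.3% of AB42 and 38.4% of IL4, and cycling progenitor-like cells 2.22%, 1.35% and 3.34%. With no filter, radial glia-like cells were 25.2%, 20.3% and 26.5%. With at most 10% mitochondrial UMIs, cycling cells were 12.5% of PBS. With each library clustered alone, radial glia-like cells were 34.7% of PBS and 18.1% of AB42, and cycling cells 2.22% of PBS, 4.94% of AB42 and 13.5% of IL4, so that AB42 no longer had the lowest share. With each cell's own marker score, neuron-like cells were 33.7% of PBS, 36.7% of AB42 and 27.7% of IL4, and cycling cells 6.33% of PBS. At resolution 1.6, cluster 6 was 15.9% of its class in AB42. At resolution 0.4, the radial glia-like clusters 1, 4 and 11 matched 1 joint cluster, so their separate shares were lost.

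Without clusters mostly of 1 library, radial glia-like cells were 32.1% and neuron-like cells 45.0% of AB42, by construction. Then cd81b was at -0.14 (radial glia-like, AB42 against IL4), FAM163A at -0.15 (neuron-like, AB42 against PBS), and her4.2 in neuron-like AB42 cells at -0.65 against PBS and -0.65 against IL4. With weighted clusters, cd81b was at -0.23, her4.2 at -0.60 and -0.87, nusap1 at -1.05 (cycling, AB42 against PBS) and calr at -0.23 (cycling, AB42 against IL4), and 12 lists stood apart in radial glia-like cells for AB42 against PBS and 5 in neuron-like cells for IL4 against PBS.

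For the mean of each cell's own CPM, immediate early genes were at -0.023 and 11 lists stood apart in radial glia-like cells (AB42 against PBS), and neuronal differentiation was at 0.083 in oligodendrocyte lineage-like cells (IL4 against PBS). In thinned cells, synapse genes were at -0.10 (radial glia-like, AB42 against IL4), 4 lists stood apart in neuron-like cells (IL4 against PBS), and in oligodendrocyte lineage-like cells (IL4 against PBS) neuronal differentiation was at 0.13, serotonin and neurotrophin receptors at -0.20 and btg1 at 0.21, and in epithelial-like cells (IL4 against PBS) ccng1 was at 0.091. Without GFP and the clone-named gene, neuronal differentiation was at 0.11 in oligodendrocyte lineage-like cells (IL4 against PBS). Without a minimum CPM, 12 lists stood apart in radial glia-like cells (AB42 against PBS) and 5 in neuron-like cells (IL4 against PBS). Neuron-like radial glia identity and serotonin and neurotrophin receptor genes were then at 0.10 and 0.012 (AB42 against PBS). In oligodendrocyte lineage-like cells neuronal differentiation was at 0.38 and neurotransmitter identity at -0.12 (IL4 against PBS) and 0.70 (AB42 against IL4), and in epithelial-like cells Id and BMP genes at -0.51. With members of at least 100 CPM, fewer of them, 6, 4 and 7 lists stood apart in neuron-like cells (AB42 against PBS, IL4 against PBS, AB42 against IL4). Radial glia identity was at 0.17 (AB42 against PBS) and endoplasmic reticulum stress at 0.33 (AB42 against IL4), and interferon response in epithelial-like cells at -0.69.

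By construction, the share of thinned radial glia-like cells with at least 1 UMI of the replication list was 96.8% in PBS, 94.4% in AB42 and 93.5% in IL4, and with at least 3 UMIs 65.8%, 61.1% and 56.5%. Unthinned it was 95.3% in PBS and 86.2% in IL4. The correlation of both ratios to PBS was 0.306 (radial glia-like) and 0.0329 (neuron-like) with split PBS cells, and 0.0425 (neuron-like) for genes of at least 200 CPM.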

Other observations

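The cells and genes in this part were looked at after the main results were seen, except the fixed lists. Cycling progenitor-like cells of both treated libraries had lower neuronal differentiation genes than those of PBS. In AB42, 11 of 17 such genes were at least 1.5-fold lower and 1 higher (median log2 ratio -0.86), with the neuronal tubulin gene tubb5 at a ratio of 0.436 (0.319 to 0.586) and the neuronal RNA-binding protein gene elavl3 at 0.465 (0.333 to 0.638). In IL4, 11 of 16 were lower and 0 higher (median -0.94), with tubb5 at 0.435 (0.334 to 0.561), elavl3 at 0.450 (0.338 to 0.593) and the proneural gene neurod1 at 0.339 (0.174 to 0.618). DNA replication and mitosis genes were higher in both, with a median of 0.24 in AB42 (9 of 36 higher and 1 lower, rrm2 2.05-fold) and of 0.30 in IL4 (11 of 37 higher and 3 lower, pcna 1.85-fold). These lists stayed apart in all 13 alternatives, which kept the classes of the main run. Markers of immature neurons were lower too, with a median of -0.86 in each, and in IL4 so were those of neurons (-0.84), endothelial cells (-1.05 over 3 genes) and radial glia (-0.24; -0.23 in AB42), and a change in the mix of cells within the class is not separated from a change within cells. Cluster 17, led by rrm2.1 and rrm2, was 15.4% of the class in PBS (8.67 to 24.5%), 7 of 46 cells in AB42 and 27.6% in IL4 (16.7 to 40.9%). With clusters weighted as in PBS the IL4 medians of neuronal differentiation and radial glia markers were -1.02 and -0.044. AB42 cells also had higher heat shock genes (median 0.36, 8 of 17), with hsp70l at 10.4-fold (7.79 to 14.2), and mitochondrially encoded genes (median 0.54), and sox2 was at a ratio of 0.228 (0.134 to 0.367). Alzheimer disease genes were lower in AB42 (median -0.56, 6 of 11 lower and 1 higher), in 11 of 12 alternatives. IL4 cells had lower Notch pathway genes (median -0.50, 9 of 19 lower and 1 higher; -0.24 in thinned cells, where they no longer stood apart), with her4.3 at 0.328 (0.282 to 0.381), and lower immediate early genes (median -0.49, 12 of 30 lower and 2 higher). In this class 5 of 24 lists stood apart for AB42 and 10 of 24 for IL4, where 1.2 would for lists of unrelated genes.

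Oligodendrocyte lineage-like cells of the treated libraries had lower myelin genes. In AB42, 7 of 9 were at least 1.5-fold lower (median -1.58), with the proteolipid gene plp1b at a ratio of 0.285 (0.220 to 0.366), and in IL4 9 of 9 (median -3.70), with plp1b at 1 against 181 UMIs. Few cells decided this: cells with at least 20 myelin UMIs were 5 of 37 in PBS, 1 of 55 in AB42 and 0 of 31 in IL4, which leaves up to 11.2%, and they held 93.0% of the myelin UMIs in PBS and 85.4% in AB42. The myelin values thus rest on the number of such cells in each library. Immediate early genes were lower in IL4 here too (median -0.59, 15 of 29 lower and 1 higher), in 11 of 13 alternatives (-0.36 in thinned cells and -0.25 for the mean of each cell's own CPM), and heat shock genes were higher in AB42 (median 0.77, 11 of 19), with hsp70l at 2.46-fold (2.06 to 2.95).

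Microglia or macrophage-like cells, 28 in AB42, 17 in IL4 and 4 in PBS, were too few for a comparison, and their levels stand here as values. The inflammatory cytokine genes il1b and tnfa were at 300 CPM (198 to 437) and 167 CPM (93.4 to 275) in AB42, and at 106 CPM (29.0 to 272) and 79.8 CPM (16.5 to 233) in IL4. Both had 0 UMIs in the 4 PBS cells, which allows up to 550 CPM, above the AB42 levels. The class joins clusters 18 and 23 in differing parts, with 82.1% of the AB42 and 52.9% of the IL4 cells in cluster 18, so differences between these levels are not separated from this mix. The apolipoprotein gene apoeb was at 2804 CPM in AB42, 452 CPM in IL4 and 2830 CPM in PBS. The receptor gene il4r.1 was at 532 CPM (325 to 821) in IL4 and 167 CPM (93.4 to 275) in AB42, and stat6 had 0 UMIs in each library. The heat shock gene hsp70l was at 4441 CPM in IL4, 657 CPM in AB42 and 894 CPM in PBS, in another order than in radial glia-like and neuron-like cells.

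Single cells carried most UMIs of several neuropeptide genes in the IL4 neuron-like cells. Of 313 UMIs of gnrh3, 99.4% lay in 1 cell, as did 99.7% of the 327 UMIs of nmbb, while 5 cells held 99.1% of those of oxt. In AB42 the 6295 UMIs of sst3 lay in 257 cells, but 5637 of them in 152 cells of cluster 6.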
